A study of Homo sapiens with 2 samples.

How the data were processed

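RNA was sequenced from 2 cultures of THP-1, a human monocytic leukaemia cell line that takes on macrophage features when given the phorbol ester PMA, an activator of protein kinase C. Per the labels' protocols, both cultures received 320 nM PMA for 6 h, and were then kept for 18 h with 0 or 50 ng/ml recombinant PTX3, the secreted long pentraxin of innate immunity. RNA was taken up in Trizol and made into libraries with the KAPA mRNA HyperPrep kit, per the labels' protocols. Each group is 1 library, called here the control library and the PTX3 library.

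The deposited count table holds the authors' unnormalized read counts per gene, as whole numbers. The second deposited table holds TPM with gene symbols, computed by the authors. Per the submitters' processing notes, the work used GRCh38, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 and DESeq, with no role or order stated. The read counter, the annotation release, the treatment of reads that map to several places and the strand setting are not given in the sources used here. In the 20282 genes with a count in both libraries, the count divided by the TPM in the control library was 1.02 times that in the PTX3 library in every gene. The TPM were therefore the same counts divided by 1 fixed length per gene and are no independent measurement.

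Both tables list 58884 Ensembl gene IDs, and no line is without a gene. Of these, 58611 were found in the GENCODE 29 annotation of GRCh38, from which gene positions and types were taken, and 273 were not. Symbols came from the TPM table, where 1945 IDs have none. A symbol held by several IDs was given to the ID with the most counts, and the others count as genes without a symbol. In the 3 cases where a symbol had been turned into a date, the GENCODE name was used.

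Library sizes were scaled by trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 0.968 for the control library and 1.03 for the PTX3 library. CPM are counts over the scaled library size in units of 1000000 counts. The ratio of each gene is that of its counts plus 0.5 over the scaled library sizes, PTX3 over control. Its 95% interval is the exact Clopper-Pearson interval of the split of the gene's counts between the libraries. With 1 library per group no test between conditions can be made, and no p-value is given. Genes were instead described by a fixed size rule: mean CPM of at least 1, a ratio of at least 2 or at most 0.5, and an interval that excludes equal levels. "Higher" and "lower" below refer to this rule unless another measure is named.

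For 36 lists of genes, the median log2 ratio of the members with mean CPM of at least 1 was set against the medians of 10000 random lists of the same size, matched on expression in 20 bins. A list is called outside the random range when its median lay beyond the central 95% of them. This places a list among the genes of these libraries and tests nothing about the conditions. Lists with under 5 such members were given as values only. All 698 distinct genes of the lists were found in the tables.

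The genes named are PTX3, the 14 higher and 14 lower genes with a gene symbol and mean CPM of at least 5 whose interval bound nearest to equal levels is farthest from it, up to 4 members of each list with the largest absolute log2 ratio and an interval excluding equal levels, members of mean CPM of at least 50 nearest to equal levels, and ACTB, GAPDH, CD14 and CD68. Other genes are marked as chosen after their values were seen. The groups, the size rule, the lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those the closing parts mark as later. The alternatives were other library scalings (DESeq2 1.42.0 size factors, total counts, upper quartile), the deposited TPM, other filters, prior counts, ratio thresholds and intervals, random lists without matching, and lists without members shared with another list.

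The rule was tested on simulated data made from the mean levels of both libraries for 13013 genes, of which 12813 were unchanged. With Poisson counting noise alone, 21 unchanged genes met it, and 97.0% of genes changed 3-fold and 100% of those changed 4-fold did so in their direction. With an assumed variation between cultures of 0.2 (coefficient of variation), 420 unchanged genes met it, and with 0.3, 1605 did. Under 0.2, with genes varying independently, 5.0% of 20-gene lists without a shift lay outside the random range. Of lists shifted by 0.5 on the log2 scale, 94.0% did. The variation between cultures in this study was not measured, so which setting applies is unknown. A variation of 0.3 in every gene gave more genes than met the rule in the 2 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.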

Results

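Messenger RNA was profiled in THP-1 macrophages with and without added PTX3, in 1 library per group. The count table gives 15074134 counts in the control library and 14586888 in the PTX3 library, and 22950 and 23236 genes with at least 1 count. Protein-coding genes took 97.2% of the counts in the control library and 97.0% in the PTX3 library. Genes of the mitochondrial genome took 10.5% (exact binomial 95% interval 10.5 to 10.6) and 11.3% (11.3 to 11.3). Because there is no replicate, the values describe these libraries and the differences have no replicate check. Intervals cover counting error only. They can be too narrow even for that, since PCR reads without molecular identifiers are not independent molecules.

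The comparison asks how gene expression of THP-1 macrophages differs after 18 h with PTX3. Among markers of mature and alternatively activated macrophages, those higher in the PTX3 library included SPP1, CSF1R, TREM2 and STAB1. The marker MARCO, chosen after its value was seen, was lower, and the markers MRC1 and CD163 had 0 CPM in both libraries. The C5a receptors C5AR1 and C5AR2 were higher as well. The inflammatory cytokine TNF, the NF-kB inhibitor TNFAIP3, the immediate early gene EGR1 and the granule protease CTSG of myeloid precursors were lower. Of 13013 genes with mean CPM of at least 1, 826 were higher in the PTX3 library and 509 were lower. At 4-fold or more, 193 were higher and 44 lower. The excess of higher genes lay at mean CPM under 20. At 1 to 5, 417 were higher and 183 lower, and at 5 to 20, 234 and 128. Against this stood 135 and 147 at 20 to 100, and 40 and 51 at 100 and over. By the counting interval alone, 3577 genes lay above equal levels and 4154 below. Most genes lay close together in both libraries, with 73.5% within 1.5-fold and a Pearson correlation across genes of 0.964 (log2 of CPM plus 0.5), genes not being independent replicates. In simulated data with an assumed variation of 0.2 between cultures, 420 of 12813 unchanged genes met the same rule. With 0.3 in every gene 1605 did, more than all genes that met it here, so that setting is too large. The variation between cultures was not measured, so these numbers describe 2 libraries and do not count genes that respond to PTX3.

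**Figure D1:**
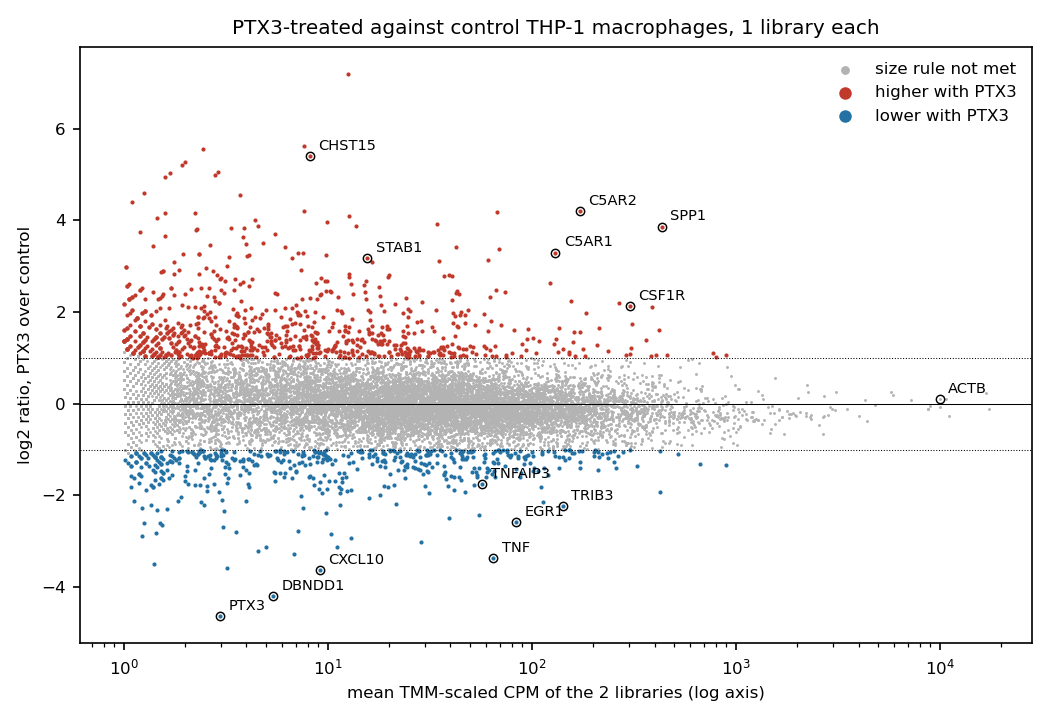
Log2 ratio of PTX3 over control (vertical axis) against mean TMM-scaled CPM of the 2 libraries (horizontal, log axis) for the 13013 genes with mean CPM of at least 1. Red points are the 826 genes higher and blue points the 509 genes lower by the size rule, dotted lines mark ratios of 2 and 0.5, and circled genes are named in the text.

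PTX3 mRNA itself (chromosome 3, 157436789 to 157443628) was lower in the library that received the protein. It had 84 counts in the control library and 3 in the PTX3 library, a log2 ratio of -4.64 with an interval of -7.16 to -3.26. Added protein brings no mRNA, so this value is the cells' own transcript. Of the 12 expressed genes of the complement and pentraxin partner list, 3 were higher, 2 lower and 7 neither. C5AR1, the receptor of the complement fragment C5a (chromosome 19, 47290023 to 47322066), stood at 24.1 CPM in the control library and 237 CPM in the PTX3 library, a log2 ratio of 3.30 (interval 3.14 to 3.46). CFP, which encodes properdin, stood at 2.95 and 9.63 CPM. CR1, the receptor of C3b, was lower at 3.49 and 0.996 CPM, and CD46 was level at 73.1 and 71.7 CPM. The list's median log2 ratio was 0.15 and its mean -0.00, and the median lay inside the random range. With mean CPM of at least 5 it was 0.48, above the range.

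Several of the genes with a symbol that lie farthest above equal levels encode surface receptors, transporters and secreted proteins. C5AR2, the other C5a receptor, lies beside C5AR1 (chromosome 19, 47332147 to 47347327) and was 18.4-fold higher, at 17.7 and 328 CPM, a log2 ratio of 4.20 (4.03 to 4.39). SPP1, the secreted phosphoprotein osteopontin (chromosome 4, 87975650 to 87983426), was 14.6-fold higher (13.6 to 15.6), at 56.0 and 815 CPM. ANGPT4, an angiopoietin (chromosome 20, 869899 to 916317), stood at 6.99 and 128 CPM. The organic anion transporter SLCO2B1 stood at 4.25 and 64.8 CPM, the amino acid transporter SLC7A8 at 12.1 and 126 CPM, and the protease inhibitor A2M at 7.26 and 78.1 CPM. HNRNPLL, an RNA-binding regulator of splicing (chromosome 2, 38561978 to 38603586), had 4 and 227 counts, a log2 ratio of 5.61 (4.41 to 7.67). CHST15, a sulfotransferase of chondroitin sulfate, had 5 and 241 counts, a log2 ratio of 5.41 (4.30 to 7.18). DHRS3, a retinal reductase, ZNF366, ADAP2, AHNAK2 and GOLGA7B complete the 14 genes with a symbol, with log2 ratios of 4.10, 4.20, 3.89, 3.96 and 3.13. Of ADAP2's exon bases, 16.7% are shared with other genes on the opposite strand.

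The genes with a symbol that lie farthest below equal levels include cytokines and transcription factors. TNF, the inflammatory cytokine (chromosome 6, 31575567 to 31578336), had 1726 and 171 counts and was 10.4-fold lower (interval 8.89 to 12.3). The chemokine CXCL10 had 247 and 20 counts, a log2 ratio of -3.64 (-4.41 to -3.01). EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), was 6.03-fold lower (5.39 to 6.77). The transcription factors NFIX and POU2F2 had log2 ratios of -3.02 and -2.49, and AFF3, a nuclear transcription cofactor, -3.12. TRIB3, a stress-induced pseudokinase, stood at 234 and 49.4 CPM, and the lysolipid transporter MFSD2A at 92.8 and 17.3 CPM. DBNDD1 had 150 and 8 counts, with a log2 ratio of -4.19. The netrin receptor UNC5C, the aspartate acetyltransferase NAT8L, LAMP5, PRRT4 and CDC42EP3 had log2 ratios of -2.93, -2.84, -2.78, -3.27 and -2.14.

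**Figure D2:**
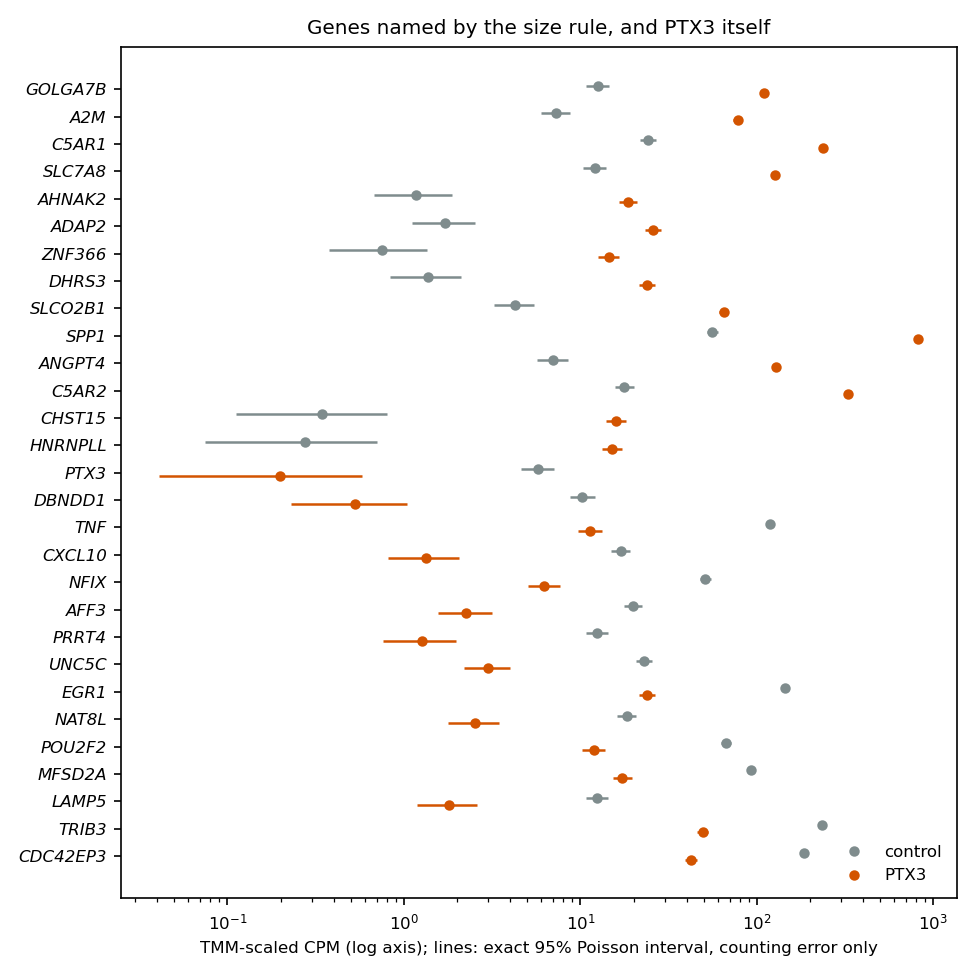
TMM-scaled CPM (log axis) in the control library (grey) and the PTX3 library (orange) for PTX3, the 14 genes named as higher and the 14 named as lower. Lines are exact 95% Poisson intervals for counting error. Those of the 2 libraries do not overlap for any of these genes, which for the genes named as higher or lower follows from how they were chosen.

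The median of the macrophage markers lay above equal levels, with members on both sides. Of the 14 expressed members of the differentiation list, 7 were higher, 1 lower and 6 neither, with a median log2 ratio of 1.01 that lay above all 10000 matched random lists. CSF1R, the receptor of the macrophage growth factor CSF1 (chromosome 5, 150053291 to 150113372), was 4.36-fold higher (interval 4.14 to 4.60), at 113 and 494 CPM. TREM2, a lipid-sensing receptor, stood at 9.45 and 39.8 CPM, and ITGAM, the CD11b integrin chain, at 71.9 and 190 CPM. MARCO, a scavenger receptor chosen after its value was seen as the lower gene of the list, had 66 and 28 counts. CD68 had 13 and 16 counts, but 85.8% of its exon bases are shared with other genes in the annotation, so its count is uncertain.

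The alternative activation list had the largest median of the 36 lists, 1.43, also above all 10000 random lists. Only 12 of its 22 genes were expressed at a mean CPM of at least 1, and of these 9 were higher, 0 lower and 3 neither. The list members MRC1 and CD163 had 0 CPM in both libraries. STAB1, a scavenger receptor (chromosome 3, 52495338 to 52524495), stood at 3.08 and 28.2 CPM, TGM2, a transglutaminase, at 0.753 and 7.44 CPM, and ALOX15, a lipoxygenase, at 2.95 and 15.3 CPM. CD209 rested on 5 and 27 counts. Of the 13 anti-inflammatory regulators, 4 were higher, 1 lower and 8 neither, with a median of 0.40 above the random range. IL10 stood at 12.3 and 34.3 CPM, its fellow list member IL1RN, the interleukin-1 receptor antagonist, at 28.9 and 65.9 CPM, and the glucocorticoid-induced TSC22D3 at 9.18 and 26.0 CPM, whereas the nuclear receptor NR4A1 stood at 44.9 and 18.2 CPM. With mean CPM of at least 5 the regulators' median was 0.24, inside the random range.

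Lists of uptake, adhesion, lysosome and matrix genes had medians above the random range, with most members meeting neither side of the rule. Among 21 expressed genes of Fc receptors and phagocytosis, 6 were higher, 0 lower and 15 neither, with a median of 0.50 above all 10000 random lists. MERTK, a receptor for apoptotic cells, stood at 18.1 and 72.1 CPM, ITGB5 at 54.1 and 257 CPM, and FCER1G, the Fc receptor gamma chain, at 60.8 and 158 CPM, while VAV1 was level at 117 and 111 CPM. Of 19 adhesion and migration genes, 4 were higher, 1 lower and 14 neither (median 0.32, above the random range). SELPLG, the ligand of P-selectin, stood at 19.0 and 78.7 CPM, and the fractalkine receptor CX3CR1 at 29.5 and 12.6 CPM. Of 23 autophagy and lysosome genes, 4 were higher, 0 lower and 19 neither (median 0.18, above the range, but inside without matching), including the proteases CTSB at 250 and 516 CPM and CTSD at 108 and 249 CPM. For CTSD, 52.7% of exon bases are shared with other genes. Of 18 matrix remodelling genes, 6 were higher, 2 lower and 10 neither (median 0.55, above all 10000 random lists). The higher genes included MMP14 at 14.1 and 67.7 CPM, MMP19 at 3.43 and 29.6 CPM, TGFBI at 1.37 and 13.7 CPM and THBS1 at 10.3 and 47.9 CPM. Intervals of 11 matrix genes lay above equal levels and of 5 below. The summed level of all genes of that list was lower, at 2970 CPM in the control library and 2571 CPM in the PTX3 library.

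The NF-kB feedback list had the lowest median of the lists. Of 20 expressed members, 0 were higher, 7 lower and 13 neither, and the intervals of 16 lay below equal levels. Their median log2 ratio of -0.91 lay below all 10000 random lists. TNFAIP3, a ubiquitin-editing inhibitor of NF-kB (chromosome 6, 137867188 to 137883312), was 3.39-fold lower (interval 3.03 to 3.81). BIRC3 stood at 19.7 and 5.25 CPM, the survival gene BCL2A1 at 81.1 and 26.8 CPM and RELB at 91.4 and 37.9 CPM, while IRAK2 was level. Inflammatory cytokines were split. Of 14 expressed members, 0 were higher, 4 lower and 10 neither, with a median of -0.07 inside the random range (0.01 with mean CPM of at least 5 and 0.02 with total counts) and a mean of -0.63. With TNF, the neutrophil chemokine CXCL8 was lower, at 149 and 53.5 CPM, as were CCL3 and CCL4, whose counts are uncertain because near-identical copies exist and because 74.6% of the exon bases of CCL3 are shared with other genes. CCL5 was level at 230 and 232 CPM.

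The medians of immediate early genes and of precursor genes lay below the random range as well. Of 22 expressed immediate early genes, 1 was higher, 10 lower and 11 neither, with a median of -0.45. With mean CPM of at least 5 it was -0.75, also below the range. EGR2, FOSB and the MAP kinase phosphatase DUSP2 had log2 ratios of -1.67, -1.68 and -1.52. KLF4, chosen after its value was seen as the higher gene of the list, had 37 and 80 counts. Of 17 monocyte and precursor genes, 1 was higher, 4 lower and 12 neither. Their median was -0.59, below all 10000 random lists, and their mean -0.18. The granule protease genes CTSG and PRTN3 stood at 132 and 46.3 CPM and at 140 and 63.8 CPM, and MS4A3, a membrane protein of myeloid precursors, at 19.0 and 4.05 CPM. CD33 was level at 106 and 105 CPM. CD14, the endotoxin co-receptor and the member of this list that was higher, had 1 and 47 counts, a log2 ratio of 4.94 (2.96 to 10.84).

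**Figure D3:**
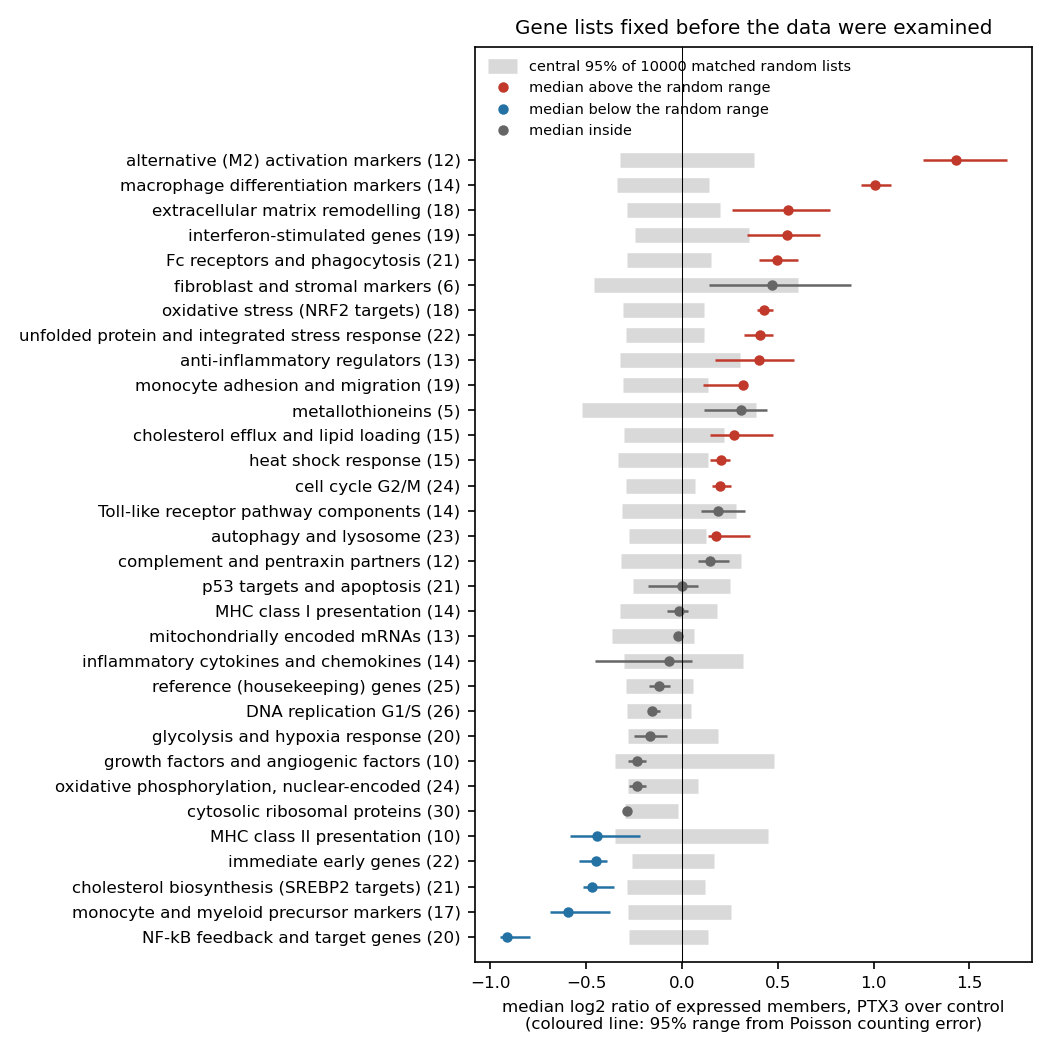
Median log2 ratio of PTX3 over control of the expressed members of each gene list (points, number of members in brackets) with its 95% range from Poisson counting error (coloured lines) and the central 95% of 10000 expression-matched random lists (grey bars). The 13 lists in red lie above their random range, the 5 in blue below it, and 14 inside.

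Pattern recognition and interferon genes gave a mixed picture. Of 14 expressed genes of the Toll-like receptor pathway, 2 were higher, 0 lower and 12 neither. Their median of 0.19 lay inside the random range (0.09 and inside with mean CPM of at least 5), and their mean was 0.86. Both of the higher genes belong to endotoxin recognition, CD14 and LY96, the TLR4 co-receptor MD-2 with 4 and 108 counts (log2 ratio 4.55, interval 3.31 to 6.61), while the adaptor MYD88 was level with a log2 ratio of 0.05. Of 19 interferon-stimulated genes, 5 were higher, 1 lower and 13 neither, with a median of 0.55 above the random range. The antiviral genes OAS1 and OAS3 stood at 1.03 and 11.3 CPM and at 8.77 and 28.2 CPM and IFIT3 at 1.03 and 4.85 CPM, against the lower CXCL10. Of 10 MHC class II genes, 1 was higher, 1 lower and 8 neither. Their median of -0.44 lay below the random range, but it was -0.37 and inside with mean CPM of at least 5, and -0.33 and inside with the deposited TPM. HLA-DRA stood at 116 and 59.5 CPM and the costimulatory CD86 at 2.53 and 5.98 CPM. Of 14 MHC class I genes, 1 was higher, 1 lower and 12 neither (median -0.02, inside the range, and 0.03 with DESeq2 size factors). B2M was level at 683 and 693 CPM.

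The medians of the lipid lists lay on opposite sides of equal levels, with few members meeting the rule. Of 15 expressed genes of cholesterol efflux and lipid loading, 3 were higher, 0 lower and 12 neither, with a median of 0.27 above the random range (0.14 and inside with mean CPM of at least 5, and also inside without matching). The cholesterol exporter ABCA1 had 11 and 134 counts, the oxidized lipoprotein receptor OLR1 16 and 112, and the nuclear receptor PPARG stood at 35.9 and 83.9 CPM. Of 21 cholesterol biosynthesis genes, 0 were higher, 1 lower and 20 neither, with 14 intervals below equal levels and a median of -0.47 below all 10000 random lists. STARD4, a sterol transfer protein, was the lower gene, with a log2 ratio of -1.06. The synthesis enzymes HMGCS1 and FDFT1 both had log2 ratios of -0.95.

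The unfolded protein, NRF2 and heat shock lists had medians above the random range with few members meeting the rule. Of 22 genes of the unfolded protein and integrated stress response, 1 was higher, 2 lower and 19 neither. Their median was 0.41, above all 10000 random lists, and their mean 0.14. SDF2L1 and DNAJC3, of protein folding in the endoplasmic reticulum, had log2 ratios of 1.08 and 0.98, whereas the lower genes were TRIB3 and the serine synthesis enzyme PSAT1 at 179 and 60.7 CPM. Of 18 NRF2 targets, 3 were higher, 0 lower and 15 neither (median 0.43, above all 10000 random lists). FTH1, the ferritin heavy chain, stood at 488 and 1058 CPM, but 62.4% of its exon bases are shared with genes on the opposite strand. Of 15 heat shock genes, 2 were higher, 0 lower and 13 neither (median 0.20, above the range, but inside without matching). The higher genes were HSPA1A and HSPA1B, near-identical copies between which reads could be divided, while HSPD1, the mitochondrial chaperonin, had a log2 ratio of -0.75. Of 5 metallothioneins, 1 was higher, 0 lower and 4 neither (median 0.31, inside the range but 0.38 and above it with the deposited TPM), and reads of this family are hard to assign.

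Of 24 G2/M genes, 1 was higher, 0 lower and 23 neither (median 0.20, above the random range, but inside without matching), with the kinetochore gene CENPE at 23.0 and 48.0 CPM. None of 26 replication genes met the rule (median -0.16, inside), where MCM7 stood at 1207 and 793 CPM and CDT1 was level. Of 21 p53 and apoptosis genes, 1 was higher and 3 lower (median -0.00, inside, and 0.04 with DESeq2 size factors). BCL2 stood at 16.4 and 33.0 CPM, and the death receptor TNFRSF10B at 197 and 74.7 CPM. Of 10 growth and angiogenic factors, 3 were higher and 3 lower, with a median of -0.23 and a mean of 0.02. EDN1, which encodes endothelin-1, had 22 and 87 counts, and HGF 45 and 11.

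In metabolism, 1 of 20 glycolysis and hypoxia genes was lower and 0 higher (median -0.17, inside the range), the hexokinase HK2 at 55.4 and 24.8 CPM. None of 24 nuclear genes of oxidative phosphorylation met the rule (median -0.23, inside), and none of 13 mitochondrial mRNAs did (median -0.02, mean 0.03, inside). All 30 cytosolic ribosomal protein genes had intervals below equal levels, but none was 2-fold lower and their median of -0.29 lay inside the random range, which for genes this abundant spans -0.30 to -0.02. Without matching on expression, the same median lay below the range. All cytosolic ribosomal protein genes together took 7.65% of the counts in the control library and 6.67% in the PTX3 library. Of 25 reference genes, none met the rule (median -0.12, inside). ACTB had a log2 ratio of 0.10 and GAPDH -0.12.

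Markers of other cell types were scarce. Only 2 of 15 T and NK cell markers, 4 of 10 B cell markers, 1 of 13 epithelial markers and 1 of 14 erythroid and megakaryocyte markers reached a mean CPM of 1, with median log2 ratios of 0.81, 0.01, 0.43 and 0.23. IL7R, which monocytic cells can also express, had 194 and 504 counts. Of 6 fibroblast and stromal markers that did so, 2 were higher, PDGFRB with 44 and 187 counts and COL6A3 with 253 and 590 (median 0.47, inside the range). In all, 18 of the 32 lists with at least 5 expressed members lay outside their random range. For lists without a shift, of genes that vary independently, 1.60 would be expected. Genes of a list can vary together between any 2 cultures, so the 1.60 is no yardstick for these lists. The same genes also occur in several lists, so the lists are not independent.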

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

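All alternatives were chosen before the data were examined, except the counts for protein-coding genes alone, which were added after the results were seen. The 826 higher and 509 lower genes became 1481 and 831 with the deposited TPM and a pseudocount of 0.1, 409 and 326 with mean CPM of at least 5, 1653 and 1460 at a ratio threshold of 1.5, and 193 and 44 at a ratio threshold of 4. Without an expression filter 1246 genes were higher and 675 lower. Filters and thresholds act through the genes they admit. The TPM settings used no counting interval and a filter of mean TPM of at least 1. As the TPM are the same counts, the difference comes from these changes, the pseudocount and the scaling, whose shares were not separated. The TPM setting shared 694 higher and 359 lower genes with those reported, and with a pseudocount of 1, which gave 1046 and 569, only 519 and 234 were shared. The other settings stayed within 1.5 times of both counts. The nearest scaling, upper quartile, gave 836 and 500, DESeq2 size factors 904 and 441, and total counts 985 and 386, which moves the share of higher genes among those meeting the rule from 61.9% to 71.8%. Protein-coding genes alone gave 636 and 426. Scalings moved the median log2 ratio of expressed genes by at most 0.09. The number of lists outside the random range was 18 with DESeq2 size factors, 16 with mean CPM of at least 5 (15 of them the same lists), 18 with the deposited TPM (17 the same) and 15 without matching (14 the same). Without matching, the lists of cholesterol efflux, heat shock, G2/M and autophagy lay inside the range. No median of the 18 lists changed sign in 198 values under alternatives. Scaling alone could turn none, as the smallest of these medians was 0.18. None of 103 named genes that met the rule changed sign in 618 values, which decides nothing. Their ratios are at least 2-fold, and other scalings, the TPM or a larger prior count could not turn them. Counting each named gene and each list once per alternative, 148 log2 ratios moved beyond their counting interval and 920 did not, and 80 medians did and 314 did not. No replicate could be left out, and no paired analysis was possible because each group has 1 library. Of the 826 higher genes, 417 had mean CPM under 5, and the effect of depth on them was not tested. No library-to-library spread was measured at any depth.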

Other observations

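The gene families in this paragraph and the next, MYC, and the tests of mixed-in tissue macrophages, the cell cycle, other culture differences and the lincRNA copies, were chosen after the results were seen. Of 20 families picked by gene symbol, 5 lay above and 6 below the range of matched random lists. Genes of ribosome assembly in the nucleolus stood furthest below. Of 38 expressed members 0 were higher and 14 lower, 37 intervals lay below equal levels, and the median log2 ratio was -0.83, below all 10000 random lists. RRP9, NOP16 and WDR12 stood at 94.9 and 32.6, 74.7 and 26.7, and 95.7 and 34.6 CPM. DKC1, the pseudouridine synthase of small nucleolar ribonucleoproteins, stood at 244 and 101 CPM. MYC, a transcription factor of growth genes, had 1149 and 419 counts. In other parts of protein synthesis the medians were -0.56 for 18 aminoacyl-tRNA synthetases (2 lower), -0.34 for 51 translation initiation factors (1 lower) and -0.33 for 75 mitochondrial ribosomal proteins (0 lower). For the 8 subunits of the chaperonin CCT, of protein folding, the median was -0.64 (1 lower). All of these lay outside the random range. The planned list of 30 cytosolic ribosomal proteins (median -0.29, 0 lower) and the 37 proteasome subunits, of protein breakdown (median -0.16), lay inside it.

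Above the range lay leukocyte immunoglobulin-like receptors, Siglecs, integrins, S100 proteins and cathepsins. Of 8 leukocyte immunoglobulin-like receptors 5 were higher and 0 lower (median 1.33), with LILRA5 at 8 and 129 counts and LILRB2 at 64 and 195, and LILRA2, the most abundant, at 4635 and 4473. Of 8 Siglecs, receptors for sialic acid, 5 were higher (median 1.05), among them SIGLEC10 at 138 and 372 counts and SIGLEC9 at 841 and 1797. Reads of these families can be divided between similar members. Of 20 integrin subunits 6 were higher (median 0.66), with ITGAL, the CD11a chain, at 185 and 430 CPM and ITGB7 at 8.36 and 24.6 CPM. S100 proteins had a median of 0.82 (2 of 13 higher), with S100A9 at 35.3 and 68.9 CPM. Cathepsins had a median of 0.35, with CTSB, CTSD and CTSO higher and CTSG lower. The 300 expressed ZNF genes had a median of -0.03, just below their range, and the other families (C-type lectins, RAB GTPases, solute carriers, ABC transporters, histones, tetraspanins, dual specificity phosphatases and V-ATPase subunits) lay inside theirs.

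The joint pattern of list medians, above the random range for macrophage and alternative activation genes and below it for precursor, NF-kB and immediate early genes, was set against technical explanations. Taking out the transcript length and GC trend left 5 of the 5 lists outside the random range, but so small a trend could hardly move them. With genes grouped by length, median log2 ratios ran from -0.053 to 0.0445, and by GC from -0.045 to 0.009. The smallest of the 5 list medians in size was -0.45. The removal therefore decides nothing, though the trend itself is far smaller than these medians. Library scaling turned the sign of 0 of the 5 medians and decides nothing either, as 1 factor moves all genes alike, here by at most 0.09. Tissue macrophages mixed in would bring C1Q, CD163, MRC1 and APOE, whose summed level in the PTX3 library was 0.996 CPM beside 815 CPM of SPP1. Withdrawal from the cell cycle would lower cycle genes. By the size rule, which needs a 2-fold drop, 0 of 24 G2/M and 0 of 26 replication genes were lower. Their medians lay at percentiles 99.93 and 38.8 of matched random lists (96.1 and 10.2 without matching). The G2/M genes as a set were not reduced, with 16 intervals above equal levels and 4 below. Of the replication intervals, however, 17 lay below equal levels and 4 above. The comparison was set after both lists were seen and they lean apart, so it does not decide on withdrawal. A first test that pooled both lists, at percentile 93.1, decided nothing either. A difference between the cultures other than PTX3, such as density, timing or library preparation, cannot be told apart from PTX3, since there is 1 library per group.

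Genes of low abundance leaned up and abundant genes down, with a median log2 ratio of 0.14 at mean CPM of 1 to 5 and -0.13 at 100 and over. The transcript length and GC trend does not account for it, as the difference was 0.28 before and 0.30 after its removal (bootstrap standard error 0.021). DNA carried into the PTX3 library could raise low genes. The 501 genes of families silent in these cells (olfactory and taste receptors and the like) had 165 and 178 counts together. Their ratio of 1.045 does not decide, as its interval of 0.841 to 1.30 holds both no difference and the 1.21-fold shift. Their level was not part of the test set in advance but does bear on it, at fewer than 1 count per gene. By comparison, 1 CPM is about 15 counts in either library. So low a background argues against DNA as the source of the shift, though the silent genes were not matched to the low genes in length. No biological explanation was tested.

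The highest ratio of any expressed gene belonged to ENSG00000281383, a lincRNA of 923 bases on the short arm of chromosome 21 (8254592 to 8255514, minus strand), with 2 and 377 counts and a log2 ratio of 7.19 (5.65 to 10.56). It is 1 of 4 copies with the same symbol, and is not among the named genes because another copy has more counts. The others each differ from it at 4 bases, and they had 0 and 1, 1171 and 565, and 1397 and 6597 counts. Reads shared between near-identical copies may have set the single ratio, since the summed counts of 2570 and 7540 gave 1.51 (1.44 to 1.57), far below it. All 4 copies lie within 18S ribosomal RNA genes or pseudogenes of RefSeq, so 18S ribosomal RNA left in the PTX3 library could be the source of the remaining difference. The 5.8S genes of the same repeats, with 15 and 20 counts and a log2 ratio of 0.36 (-0.67 to 1.44), are too few in counts to decide.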
